A study of Rattus norvegicus with 9 samples.

How the data were processed

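RNA sequencing libraries of HEI-OC1 cells were compared, 9 in all, 3 from cells given phosphate-buffered saline (PBS), 3 from cells given neomycin and 3 from cells given cisplatin, each for 24 h per the labels. Groups and replicate numbers were taken from the sample titles. The cell-line label carries a different final number in every sample, while the series design names HEI-OC1 alone, so the 9 samples were treated as 1 line. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Doses are not given in the sources used here.

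Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with an mRNA sequencing kit that builds full-length cDNA. The deposited table gives FPKM values (fragments scaled to gene length and to the mapped fragments of the library) computed by the authors, per the file headers, for 19608 genes, of which 16136 were annotated as protein-coding and 3472 as non-coding. The aligner and counter are not given in the sources used here. The sources disagree about the organism. The labels and the annotation columns of the table (Entrez, KEGG and Reactome identifiers) are those of rat, HEI-OC1 is known as a mouse line, and the submitters' processing notes name the mouse build mm10. Of the gene identifiers, 18532 (94.5%) were found in a rat reference table of the assembly GRCr8, which was used only to match older gene symbols. Because the build of the values is uncertain, no coordinates are given. If reads of one species were placed on gene models of the other, genes with diverged sequences would read low in every library, so levels are compared between libraries and not between genes.

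In each library the FPKM values of a gene are whole multiples of the value of 1 read. Whole reads were worked out from these steps for 19606 of the 19608 genes (100.0%), within a tolerance of 0.001 of a read. The scaling totals found in this way lay between 27516629 and 40221089 reads per library, and the genes of the table held 99.95 to 99.97% of them. On a gene of 1 kb 3 reads correspond to between 0.0746 and 0.109 FPKM, depending on the library. Every tested gene had at least 99 reads summed over the 9 libraries.

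The main test was fixed before the data were examined. Genes with a mean of at least 1 FPKM over all libraries (10532 genes) were tested on log2(FPKM + 1) with limma, with 1 mean per group, all 9 libraries in the fit and a mean-variance trend, followed by Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A total of 34 gene lists were written before the data were examined, and lists with at least 5 tested members were compared with the other genes by limma's camera with a preset correlation of 0.01. Of their 1018 members 969 were matched to the table, 8 of them by an older symbol. No camera call in the 3 comparisons held with a correlation estimated from the data. KEGG terms printed in the deposited table (309 terms with 10 to 300 tested genes) were tested in the same way after the data were examined.

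Named genes followed a rule written in advance. The rule took, for each drug against PBS, the 10 called genes with the largest rise and the 10 with the largest fall that reached 5 FPKM in the higher group and had replicates that did not overlap. Predicted genes and pseudogenes were left out, which here also covered names made of RGD and digits or ending in Rikl. For cisplatin against neomycin it took 5 in each direction. It also took up to 4 called members per list by size, and a fixed set of stress, cell cycle and hair cell genes, of which Atoh1, Sox2 and some others were not analysed here. Some list members that the rule took were also not used here. Genes outside the rule are marked as chosen after their values were seen.

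Overlap between the drugs was set beside 100 simulations of unchanged groups that share the PBS libraries, and beside the overlap of independent lists. The gene test and the list test were checked only after the main test had been run on the real values. Both were run on simulated data, with reads drawn at the real means and depths and 50 genes changed at each of 4 known folds. Every simulated gene had the same spread between replicates (a dispersion of 0.0016). The recovery of whole reads and the alternative settings were not checked in this way. For cisplatin against PBS, 35 of 50 genes changed 1.2-fold, 49 of 50 changed 1.5-fold and 50 of 50 changed 2-fold were recovered, and 10 unchanged genes of 10529 in the fit were called. For neomycin against PBS, 37 of 50 were recovered at 1.2-fold and 50 of 50 at 1.5-fold, and 15 unchanged genes of 10520 in the fit were called. For cisplatin against neomycin, 38 of 50 were recovered at 1.2-fold and 50 of 50 at 1.5-fold, and 18 unchanged genes of 10518 in the fit were called. A list raised on purpose was called in each, and 0 of 20 other lists were. Simulated genes were drawn independently of each other, so the list result does not test the preset correlation. Far fewer genes were changed than differed in the real data, so the scaling was not tested either.

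Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, quantile normalization, scaling factors from a trimmed mean of log ratios (TMM) computed on the FPKM values, a fit of only the groups compared, array weights, no variance trend, the replicate number as a block, a test against a 1.5-fold change (limma's treat), and leaving out each library. For gene lists, fry and an estimated correlation were also run. A limma voom fit on the recovered whole reads was added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.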

Results

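HEI-OC1 is a line of immortalized cells from the organ of Corti, the sensory epithelium of the cochlea, and is used as a hair cell-like model. The study asked how cisplatin, a platinum drug that crosslinks DNA, and neomycin, an aminoglycoside antibiotic, change gene expression in these cells. Both drugs damage hearing. The data are FPKM values of 3 libraries each from cells given PBS, neomycin or cisplatin for 24 h. The scaling totals, recovered from the values, were 32510698, 34398239 and 38243593 reads for PBS replicates 1 to 3, 28397694, 27516629 and 34249663 for neomycin and 33109128, 38707843 and 40221089 for cisplatin.

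The 9 libraries separated by treatment. The first principal component of log2(FPKM + 1) held 75.7% of the variance and set the cisplatin libraries (41.4 to 44.2) apart from PBS (-15.6 to -15.0) and neomycin (-28.3 to -26.4). The second held 19.6% and set neomycin (16.3 to 17.9) apart from PBS (-21.1 to -20.2). Replicates of a group differed by more than the sampling noise of their reads, with a chi-square per degree of freedom of 4.23 to 14.16, so no library was a copy of another. Both PBS pairs with replicate 1 gave high values (12.23 and 14.16), against 4.23 for replicates 2 and 3.

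**Figure D1:**
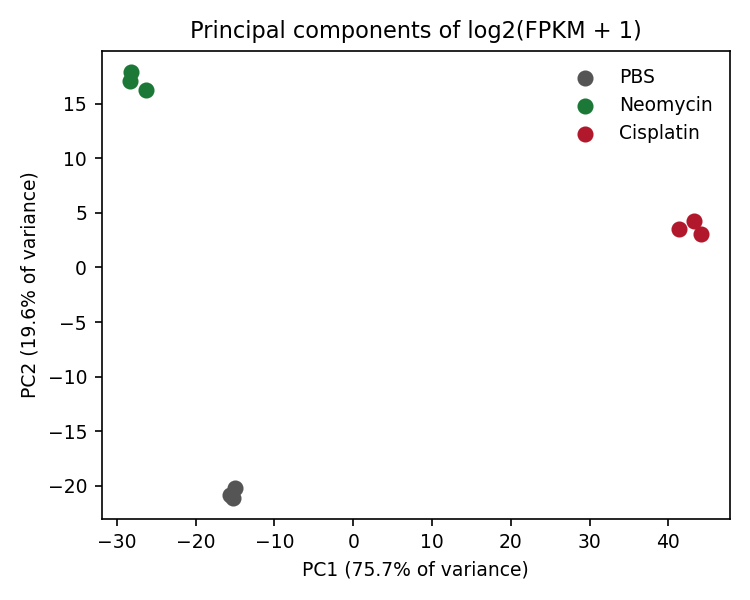
Scores of the 9 libraries on principal components 1 and 2 of log2(FPKM + 1), 3 libraries per treatment, with the share of variance on each axis. Each treatment forms its own group, and cisplatin lies at 41.4 to 44.2 on the first component.

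Cells given cisplatin carried more mRNA of immediate early and inflammatory genes than cells given PBS. Maff (Entrez gene 366960), a small MAF transcription factor, rose from 8.18 ± 0.37 to 115 ± 8.35 FPKM (mean ± SD, n = 3 per group), a log2 fold change of 3.66 ± 0.06 (SE; limma adjusted p = 6.1e-14). The stress sensors Gadd45g (log2 fold change 3.56 ± 0.08) and Gadd45b (2.99 ± 0.07), endothelin Edn1 (3.56 ± 0.10) and the EGF receptor ligand Hbegf (3.28 ± 0.09) were also among the 10 largest rises. Of 26 tested fibroblast and matrix genes 18 fell and 8 rose, and the collagen chain Col1a1 fell from 1996 ± 69.5 to 452 ± 21.7 FPKM (log2 fold change -2.14 ± 0.05, adjusted p = 1.7e-13).

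In all, 8216 of the 10532 tested genes (78.0%) differed between cisplatin and PBS, 5001 higher and 3215 lower, and 624 were at least 2-fold higher and 354 at least 2-fold lower. The median gene moved by 0.12 on the log2 scale, and TMM factors lowered the cisplatin changes by a median of 0.12, less for low genes, so changes of this size depend on the scaling. With TMM factors the calls divided evenly, 4068 higher and 4034 lower, or 50.2% higher against 60.9% on the values as deposited. The 2-fold calls then numbered 449 higher and 475 lower. Such small shifts passed the test because the median standard error was 0.06.

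The 10 largest rises also took in the chemokine genes Cxcl2 (log2 fold change 3.09 ± 0.08) and Ccl7 (2.79 ± 0.09), the urokinase receptor Plaur (2.88 ± 0.08), the AP-1 subunit Fos (2.81 ± 0.11) and Tnfaip3 (2.81 ± 0.05), a brake on NF-kB. Of 19 tested immediate early genes 17 rose and 1 fell, 15 of the rises being at least 2-fold. Examples beside Maff and Fos were Btg2 (log2 fold change 2.71 ± 0.07) and Fosl1 (2.42 ± 0.09). The list stood above other genes (camera adjusted p = 7.3e-06; adjusted p = 0.272 with an estimated correlation). Among 22 NF-kB and cytokine genes 19 rose and 2 fell, with Ccl2 at 42.8 ± 3.41 FPKM in PBS and 277 ± 14.9 FPKM in cisplatin (camera adjusted p = 8.2e-05; adjusted p = 0.241 with an estimated correlation). The counts for both lists were the same adjusted over the list alone.

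The cell cycle inhibitor Cdkn1a (Entrez gene 114851) rose from 17.3 ± 1.30 to 35.5 ± 0.45 FPKM, a log2 fold change of 1.00 ± 0.06 (limma adjusted p = 3.5e-09), and the ubiquitin ligase Mdm2 by 0.97 ± 0.07 on the log2 scale. The p53 target list as a whole was not called. Of its 22 tested genes 11 rose, led by Btg2, Plk2 (2.51 ± 0.08) and Plk3 (1.35 ± 0.05), and 5 fell, led by Sesn2 (-1.42 ± 0.06; camera adjusted p = 0.279; 11 and 4 adjusted over the list alone). Bax, a pore-forming death protein, rose by 0.36 ± 0.06. Of 23 pro-apoptotic genes 13 rose, including the BH3-only gene Pmaip1 (1.09 ± 0.06), and 4 fell, including Bcl2l11 (-1.01 ± 0.06). Of 9 anti-apoptotic genes 5 rose and 2 fell, with Birc3 at 2.32 ± 0.07. Neither list was called by camera (adjusted p = 0.340 and 0.273). Gdf15, also fixed in advance, stayed under the filter, at 0.85 FPKM in PBS and 1.04 FPKM in cisplatin.

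Cell cycle and repair genes rose together with Cdkn1a. Of 40 replication genes 32 rose and 2 fell, including the helicase subunit Cdc45 (log2 fold change 1.94 ± 0.05) and the helicase loaders Orc1 (1.90 ± 0.08) and Cdc6 (1.67 ± 0.05; camera adjusted p = 1.0e-05; adjusted p = 0.261 with an estimated correlation). Among 35 mitosis genes 30 rose and 3 fell, with Aurkb at 1.87 ± 0.04 (camera adjusted p = 2.6e-04; adjusted p = 0.272 with an estimated correlation). Mki67 rose by 0.47 ± 0.07, Ccnd1 by 1.07 ± 0.05 and Ccnb1 by 0.23 ± 0.04, and the last was not called under quantile normalization (adjusted p = 0.255). Of 36 DNA repair genes 23 rose and 3 fell, among them the Fanconi genes Fancb (1.89 ± 0.09) and Ube2t (1.61 ± 0.05) and the recombination nuclease Exo1 (1.58 ± 0.06; camera adjusted p = 0.0218; adjusted p = 0.241 with an estimated correlation). Counts adjusted over the list alone were the same for these lists. Replication-dependent histones were mixed, 11 higher and 4 lower of 15 (camera adjusted p = 0.522), and are uncertain because near-identical copies share reads.

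Ribosome assembly, mitochondrial ribosomal, respiratory chain, proteasome and heat shock lists were also higher. Of 25 nucleolar ribosome assembly genes 24 rose and 1 fell, led by Nop56 (1.26 ± 0.06) and Wdr12 (1.08 ± 0.06; camera adjusted p = 2.0e-04; adjusted p = 0.301 with an estimated correlation). Mitochondrial ribosomal proteins rose in 57 of 71 cases and fell in 5, with Mrpl38 at 1.55 ± 0.05 (camera adjusted p = 2.6e-04; adjusted p = 0.317 with an estimated correlation). Nuclear respiratory chain genes rose in 54 of 78 cases and fell in 7, by small amounts such as 0.77 ± 0.06 for Ndufv2 (camera adjusted p = 0.0034; adjusted p = 0.400 with an estimated correlation). Of 37 proteasome subunits 30 rose and 4 fell (31 and 4 adjusted over the list alone), with Psma1 at 0.99 ± 0.06 (camera adjusted p = 0.0142; adjusted p = 0.400 with an estimated correlation), and TMM factors ended this call (adjusted p = 0.0674). Of 17 heat shock genes 14 rose and 2 fell (14 and 3 adjusted over the list alone), including the small heat shock protein Cryab (1.85 ± 0.08; camera adjusted p = 0.0142; adjusted p = 0.261 with an estimated correlation). The other counts of these lists were the same when adjusted over the list alone.

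The largest falls were those of Gpc6, a glypican (17.9 ± 1.66 to 0.32 ± 0.07 FPKM, log2 fold change -3.84 ± 0.08), the growth factor binding protein Igfbp5 (-2.90 ± 0.07), the cadherin Cdh13 (-2.82 ± 0.06), Akr1c14 (-2.69 ± 0.07), the receptor phosphatases Ptprg (-2.65 ± 0.07) and Ptprk (-2.48 ± 0.07), the collagenase Mmp13 (-2.57 ± 0.09), Scara5 (-2.46 ± 0.04), Gas1 (-2.45 ± 0.07) and Dock1 (-2.42 ± 0.07). Of 26 fibroblast and matrix genes 18 fell and 8 rose (camera adjusted p = 0.0014; adjusted p = 0.394 with an estimated correlation). The risers included Ccn2 (2.76 ± 0.08) and Ccn1 (1.77 ± 0.10). The 6 matrix and cytoskeleton genes Col1a1, Col1a2, Col3a1, Fn1, Sparc and Vim, a set chosen after values were seen, took 4.46 ± 0.13% of reads in PBS and 1.63 ± 0.07% in cisplatin (SD, n = 3).

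Several stress-response lists fell with cisplatin. Of 29 ATF4 and integrated stress response genes 21 fell and 4 rose, among them Slc7a11 (-1.74 ± 0.08), the cystine carrier, Ddit4 (-1.65 ± 0.07), Trib3 (-1.60 ± 0.10) and Sesn2 (camera adjusted p = 1.0e-05; adjusted p = 0.349 with an estimated correlation). Ddit3 (CHOP), of the same list, rose by 0.43 ± 0.06, and Atf3 was at 25.8 ± 2.86 FPKM in PBS and 28.1 ± 0.63 FPKM in cisplatin (log2 fold change 0.12 ± 0.07, adjusted p = 0.13). Atf3 was called without PBS replicate 1 (adjusted p = 0.0087), with array weights (0.0091) and with the replicate block (0.0406). Of 24 endoplasmic reticulum stress genes 14 fell and 5 rose, with Atf6 at -1.29 ± 0.05 and the chaperone Hspa5 at -0.82 ± 0.05 (camera adjusted p = 0.0101; adjusted p = 0.241 with an estimated correlation). Of 23 NRF2 targets 14 fell and 7 rose, with Gclc, the first enzyme of glutathione synthesis, at -1.73 ± 0.04 and Hmox1 at 0.33 ± 0.04 (camera adjusted p = 0.008; adjusted p = 0.261 with an estimated correlation). Of 24 cholesterol synthesis genes 14 fell and 6 rose, with Srebf2 at -0.91 ± 0.05 and Idi1 at 1.58 ± 0.07 (camera adjusted p = 0.0342; adjusted p = 0.400 with an estimated correlation), and the call was lost without cisplatin replicate 3 (adjusted p = 0.0522). The counts of these 4 lists were the same adjusted over the list alone.

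The remaining lists were not called for cisplatin. They divided as 15 higher and 3 lower of 21 interferon genes (camera adjusted p = 0.172), 49 and 10 of 77 cytosolic ribosomal proteins (0.157; 22 and 12 with TMM factors), 13 and 17 of 35 lysosomal proteins (0.241), 8 and 12 of 26 autophagy genes (0.159), 8 and 9 of 18 ferroptosis genes (0.241), 9 and 7 of 19 antioxidant enzymes (0.766), 8 and 7 of 18 glycolysis genes (0.522), 3 and 5 of 13 mitochondrially encoded genes (0.376), 5 and 6 of 14 supporting cell genes (0.322) and 4 and 8 of 12 drug handling genes (0.0776). Adjusted over the list alone these counts were the same, except 2 and 5 for the mitochondrially encoded genes. With TMM factors antioxidant enzymes divided as 8 and 9, glycolysis genes as 4 and 9 and mitochondrially encoded genes as 1 and 7. The median, the mean and the camera direction differed in sign for the lysosomal, antioxidant and glycolysis lists. Within drug handling, the efflux pump gene Abcb1b rose by 1.85 ± 0.06 and Abcc4 (-2.09 ± 0.05) and the endocytic receptor Lrp2 (-1.09 ± 0.06) fell. The copper and cisplatin carrier Slc31a1 rose by 0.24 ± 0.04, which was not called under quantile normalization (adjusted p = 0.259).

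**Figure D2:**
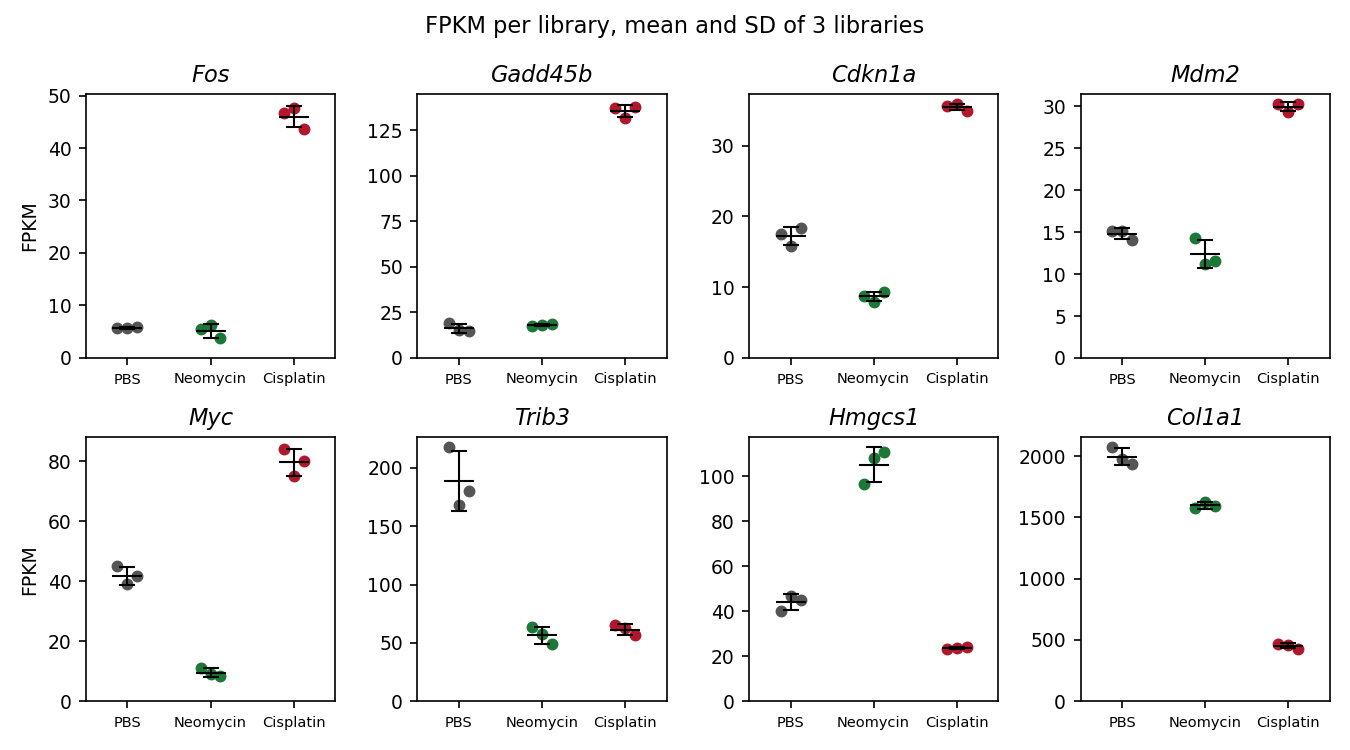
FPKM of 8 genes in the 9 libraries, with a point per library and the mean and SD of 3 libraries per treatment on a linear axis from 0. Cdkn1a and Myc lie above PBS with cisplatin and below PBS with neomycin, Hmgcs1 shows the opposite order, and Trib3 lies below PBS with both drugs.

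Cells given neomycin had higher mRNA of the cholesterol pathway and of lysosomal proteins and lower mRNA of Myc, of ATF4 targets and of ribosome assembly factors. Hmgcs1 (Entrez gene 29637), an early enzyme of cholesterol synthesis, rose from 43.9 ± 3.56 to 105 ± 7.72 FPKM, a log2 fold change of 1.24 ± 0.06 (limma adjusted p = 2.5e-09). Myc fell from 41.8 ± 3.02 to 9.55 ± 1.47 FPKM (log2 fold change -2.03 ± 0.08, adjusted p = 6.0e-10), and Trib3, an ATF4 target, from 189 ± 25.9 to 56.6 ± 7.31 FPKM (-1.72 ± 0.10, adjusted p = 7.0e-09).

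Of the 10532 genes 6973 (66.2%) differed between neomycin and PBS, 3953 higher and 3020 lower. With TMM factors 3431 were higher and 3572 lower, 49.0% higher against 56.7% on the values as deposited. Changes were small, with a median size of 0.34 on the log2 scale among called genes, and 114 genes were at least 2-fold higher and 68 at least 2-fold lower (94 and 89 with TMM factors, 97 and 96 with quantile normalization). A test against a 1.5-fold change called 426 genes. The 2-fold count rose to 380 with a pseudocount of 0.1, which shrinks the change of low genes less than a pseudocount of 1, and to 418 with voom on the recovered reads.

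The largest rises were those of the troponin Tnnt2 (log2 fold change 2.11 ± 0.07), Clec3b (2.01 ± 0.08), Fam180a (1.88 ± 0.11), the water channel Aqp1 (1.87 ± 0.10), the transcription factor Zbtb20 (1.81 ± 0.08), Sult1a1 (1.69 ± 0.09), the histones Hist1h2ah (1.68 ± 0.12) and H1f4 (1.68 ± 0.08), Hrct1 (1.68 ± 0.10) and Cryab (1.57 ± 0.08). The largest falls were those of the linker histone H1f2 (-2.75 ± 0.05), the chemokines Cxcl3 (-2.52 ± 0.08) and Cxcl1 (-1.50 ± 0.06), Myc, Hist1h2bq (-1.85 ± 0.07), Trib3, the protease Adamts1 (-1.68 ± 0.07), the proline synthesis enzyme Pycr1 (-1.64 ± 0.06), Spry1 (-1.59 ± 0.08) and H1f0 (-1.50 ± 0.06). Histone values are uncertain because near-identical copies share reads, and of the 15 tested replication-dependent histones 6 rose and 6 fell (camera adjusted p = 0.588).

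All 24 tested cholesterol genes rose, 5 of them at least 2-fold (camera adjusted p = 8.1e-11; adjusted p = 0.151 with an estimated correlation), and with TMM factors 23 did. Beside Hmgcs1, Dhcr7 rose by 1.22 ± 0.06, Acat2 by 1.13 ± 0.05 and Mvd by 1.09 ± 0.06. Of 35 lysosomal genes 27 rose and 1 fell, including the hydrolases Hexa (0.69 ± 0.05), Tpp1 (0.58 ± 0.05) and Gaa (0.55 ± 0.05) and the cholesterol carrier Npc2 (0.61 ± 0.04; camera adjusted p = 6.2e-06; adjusted p = 0.311 with an estimated correlation). Both lists gave the same counts adjusted over the list alone.

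All 29 tested ATF4 and integrated stress response genes fell, 10 of them at least 2-fold (camera adjusted p = 2.5e-16; adjusted p = 0.172 with an estimated correlation). Besides Trib3 they took in Chac1 (-1.42 ± 0.06), the amino acid carrier Slc7a5 (-1.30 ± 0.06), Atf3 (-1.28 ± 0.07) and Ddit3 (-1.08 ± 0.06). All 25 ribosome assembly genes fell as well, with Rrp12 at -1.09 ± 0.07, Gar1 at -0.99 ± 0.06, Heatr1 at -0.99 ± 0.06 and Nop58 at -0.97 ± 0.05 (camera adjusted p = 3.3e-12; adjusted p = 0.151 with an estimated correlation). Of 24 endoplasmic reticulum stress genes 9 fell and 3 rose, among them Herpud1 (-0.99 ± 0.06), Xbp1 (-0.71 ± 0.05) and Hspa5 (-0.54 ± 0.05; camera adjusted p = 0.0294; adjusted p = 0.188 with an estimated correlation). Counts adjusted over the list alone were the same for these 3 lists.

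Of the 13 protein genes of mitochondrial DNA 12 fell and ND6 rose, and the counts were the same adjusted over the list alone (camera adjusted p = 8.3e-05; adjusted p = 0.188 with an estimated correlation). COX2 fell from 12305 ± 499 to 7502 ± 290 FPKM (log2 fold change -0.71 ± 0.05), and quantile normalization gave it no change (0.00) because it was the highest gene of every library. ND3 fell by 0.67 ± 0.05 and ND1 by 0.66 ± 0.06 on the log2 scale. ND6 was at 111 ± 12.6 FPKM in PBS and 267 ± 22.2 FPKM in neomycin (1.26 ± 0.08). It lies on the other strand from its neighbours, and whether the counting used strand is not given in the sources used here. The 13 genes took 5.50 ± 0.10% of reads in PBS, 4.02 ± 0.10% in neomycin and 5.61 ± 0.19% in cisplatin (SD, n = 3). Mitochondrial ribosomal proteins fell in 40 of 71 cases and rose in 8, with Mrpl1 at -1.01 ± 0.07 (camera adjusted p = 7.0e-05; adjusted p = 0.311 with an estimated correlation), while nuclear respiratory chain genes divided as 21 higher and 23 lower of 78 (camera adjusted p = 0.349; 20 and 22 adjusted over the list alone; 12 and 31 with TMM factors).

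Proliferation genes were higher with neomycin although Myc was lower. Mki67 rose from 32.3 ± 3.18 to 76.7 ± 3.74 FPKM (log2 fold change 1.23 ± 0.07) and Ccnd1 by 1.12 ± 0.05. Of 35 mitosis genes 29 rose and 2 fell, including the kinetochore genes Cenpf (1.32 ± 0.09) and Cenpe (1.01 ± 0.09; camera adjusted p = 1.7e-06; adjusted p = 0.172 with an estimated correlation). Of 40 replication genes 27 rose and 4 fell, with Fen1 at 0.96 ± 0.05 (camera adjusted p = 0.0033; adjusted p = 0.352 with an estimated correlation), and of 36 repair genes 22 rose and 4 fell, with Fancg at 1.10 ± 0.07 and Brip1 at 1.05 ± 0.09 (camera adjusted p = 0.0117; adjusted p = 0.151 with an estimated correlation). These 3 lists had the same counts adjusted over the list alone. Cdkn1a fell from 17.3 ± 1.30 to 8.69 ± 0.69 FPKM (-0.91 ± 0.06) and Mdm2 by 0.25 ± 0.07 on the log2 scale, and of 22 p53 targets 9 rose and 7 fell (camera adjusted p = 0.573). Bax was at 103 ± 4.03 FPKM in PBS and 107 ± 8.69 FPKM in neomycin (adjusted p = 0.335), and was called without neomycin replicate 3 (adjusted p = 0.0306).

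Smaller list shifts with neomycin were 9 lower and 5 higher of 19 immediate early genes (camera adjusted p = 0.0196; adjusted p = 0.542 with an estimated correlation), led by Myc, Klf4 (-1.38 ± 0.05) and Atf3, 34 lower and 13 higher of 77 cytosolic ribosomal proteins (camera adjusted p = 0.0096; adjusted p = 0.784 with an estimated correlation), 20 lower and 7 higher of 37 proteasome subunits (camera adjusted p = 0.0131; adjusted p = 0.542 with an estimated correlation), and 11 higher and 2 lower of 21 interferon genes (camera adjusted p = 0.0272; adjusted p = 0.311 with an estimated correlation), led by Dhx58 (0.96 ± 0.07). Adjusted over the list alone the counts were 33 and 13 for cytosolic ribosomal proteins, 10 and 1 for interferon genes and the same for the others. Without neomycin replicate 3 the calls of the immediate early list (adjusted p = 0.0682) and of the cytosolic ribosomal list (0.0834) were lost. The proteasome risers included the inducible subunits Psmb8 (0.91 ± 0.07) and Psmb9 (0.69 ± 0.04).

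Other lists were not called for neomycin. They divided as 7 higher and 9 lower of 22 NF-kB genes (camera adjusted p = 0.122, and 0.0488 without neomycin replicate 1), 9 and 8 of 23 NRF2 targets (0.998), 7 and 8 of 19 antioxidant enzymes (0.588), 5 and 6 of 17 heat shock genes (0.617), 10 and 7 of 23 pro-apoptotic genes (0.79), 4 and 2 of 9 anti-apoptotic genes (0.427), 11 and 6 of 26 autophagy genes (0.766), 5 and 9 of 18 ferroptosis genes (0.209), 9 and 7 of 18 glycolysis genes (0.574; 9 and 8 adjusted over the list alone), 14 and 7 of 26 matrix genes (0.392), 3 and 7 of 14 supporting cell genes (0.15) and 3 and 5 of 12 drug handling genes (0.427). Adjusted over the list alone the other counts were the same. With TMM factors p53 targets divided as 9 and 9, NRF2 targets as 9 and 9 and pro-apoptotic genes as 8 and 8. The median, the mean and the camera direction differed in sign for the p53, histone, NRF2, antioxidant, heat shock and drug handling lists. Hmox1 was at 39.0 ± 1.25 FPKM in PBS and 38.7 ± 0.39 FPKM in neomycin (adjusted p = 0.814) and Slc31a1 at 41.4 ± 0.77 and 43.7 ± 1.33 FPKM (adjusted p = 0.113, and 0.0436 with array weights). Among single genes of these lists, the glutathione transferase Gstp1 rose by 1.02 ± 0.04, the collagen VI chain Col6a1 by 1.32 ± 0.06 and the Notch ligand Jag1 fell by 1.09 ± 0.06 on the log2 scale.

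**Figure D3:**
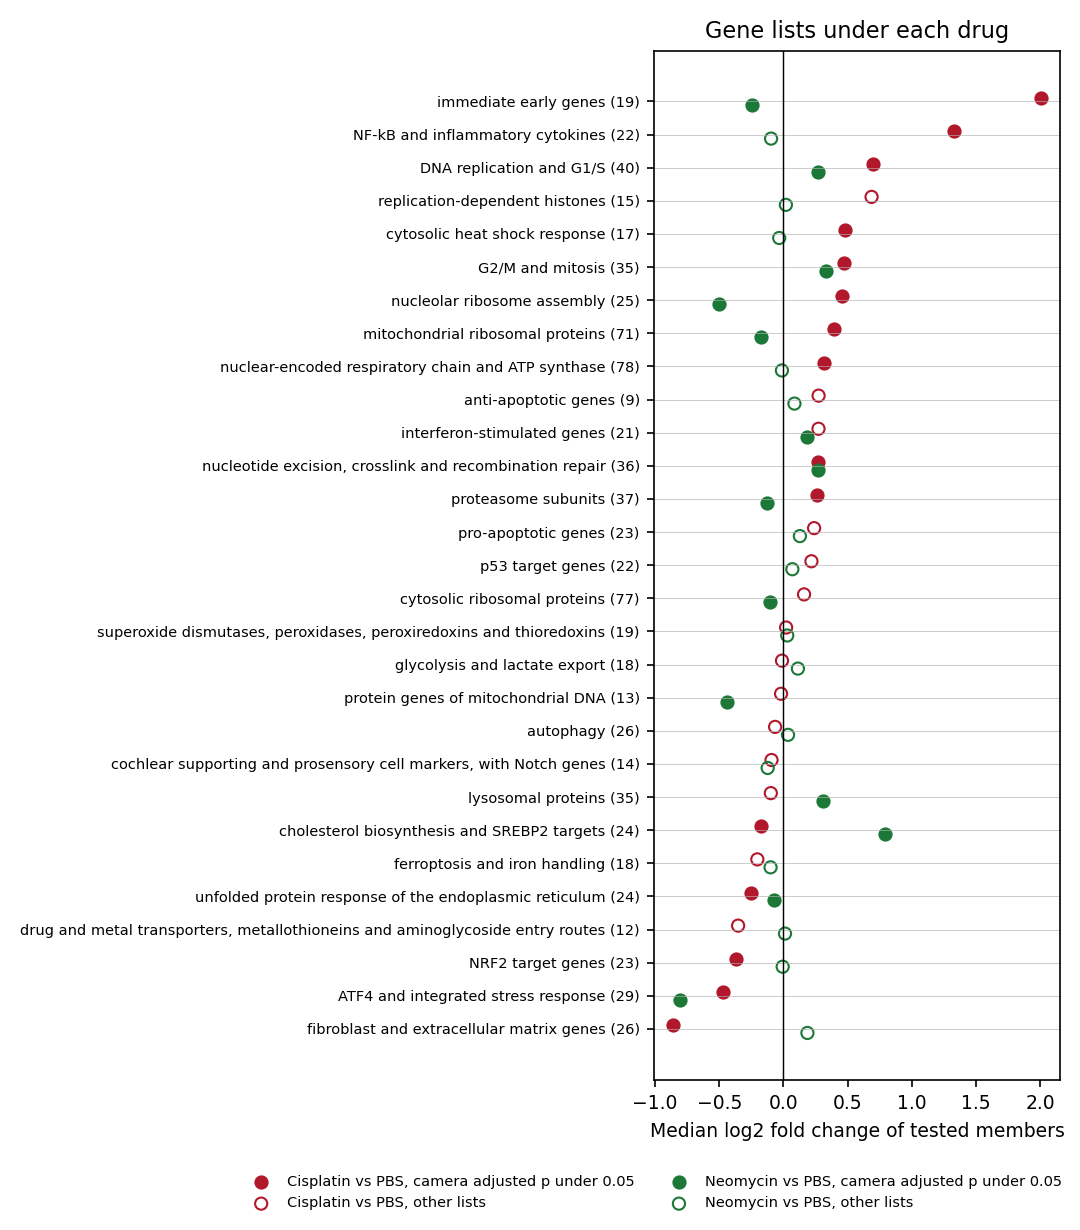
Median log2 fold change of the tested members of 29 gene lists, with their number in brackets, for cisplatin against PBS (red) and neomycin against PBS (green). Filled points are lists called by camera at the preset correlation, such as ribosome assembly at 0.45 with cisplatin and -0.50 with neomycin.

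Set directly against each other, immediate early, inflammatory and ribosome assembly genes were higher with cisplatin and most cholesterol, lysosomal and matrix genes were higher with neomycin. Gadd45g was at 7.52 ± 0.56 FPKM with neomycin and 148 ± 6.66 FPKM with cisplatin (log2 fold change 4.13 ± 0.08, limma adjusted p = 4.8e-14). Plk2 (3.75 ± 0.08), Hbegf (3.69 ± 0.09), Edn1 (3.62 ± 0.10) and Ccl2 (3.42 ± 0.07) followed. Gpc6 (-3.82 ± 0.08), Clec3b (-3.44 ± 0.08), Cdh13 (-3.37 ± 0.06), the collagen Col23a1 (-2.89 ± 0.07) and Akr1c14 (-2.87 ± 0.07) were lowest with cisplatin relative to neomycin. In all 8598 genes differed, 4740 higher with cisplatin and 3858 lower, and 793 and 623 of them by at least 2-fold. With TMM factors 4303 were higher and 4260 lower, and at 2-fold 651 were higher and 720 lower, so at 2-fold the direction that held more genes depended on the scaling.

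All 19 immediate early genes were higher with cisplatin than with neomycin, with Myc at 2.94 ± 0.08 and Klf10 at 2.91 ± 0.05 (camera adjusted p = 1.9e-08; adjusted p = 0.242 with an estimated correlation). The same held for all 25 ribosome assembly genes, with Nop56 at 2.08 ± 0.06 (camera adjusted p = 1.9e-08; adjusted p = 0.242 with an estimated correlation). Of 22 NF-kB genes 21 were higher and 1 lower (camera adjusted p = 5.3e-07; adjusted p = 0.242 with an estimated correlation), among them Ptgs2 (3.36 ± 0.05) and Il6 (3.24 ± 0.11). Mitochondrial ribosomal proteins were higher in 58 of 71 cases and lower in 4 (camera adjusted p = 4.5e-07; adjusted p = 0.242 with an estimated correlation). Of 24 cholesterol genes 23 were lower and 1 higher, 11 of the former by at least 2-fold, including Hmgcs1 (-2.11 ± 0.06), Dhcr7 (-1.78 ± 0.06) and Fdps (-1.61 ± 0.05; camera adjusted p = 1.1e-07; adjusted p = 0.242 with an estimated correlation). Adjusted over the list alone these counts were the same.

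Lysosomal genes were lower with cisplatin in 26 of 35 cases and higher in 7, with Gaa at -1.80 ± 0.05 and Psap at -1.11 ± 0.05 (camera adjusted p = 0.0014; adjusted p = 0.501 with an estimated correlation). Matrix genes were lower in 18 of 26 cases and higher in 6, with Col6a1 at -2.22 ± 0.06 and Ccn2 at 2.83 ± 0.08 (camera adjusted p = 0.002; adjusted p = 0.501 with an estimated correlation). NRF2 targets were lower in 16 of 23 cases and higher in 6, with Gclc at -1.42 ± 0.04, Pgd at -1.40 ± 0.04 and Nqo1 at -0.99 ± 0.04 (camera adjusted p = 0.0083; adjusted p = 0.242 with an estimated correlation). Higher with cisplatin were 56 of 78 respiratory chain genes against 12 lower (camera adjusted p = 0.002), 27 of 37 proteasome subunits against 5 (0.002; 28 and 5 adjusted over the list alone), 27 of 40 replication genes against 6 (0.0057), 52 of 77 cytosolic ribosomal proteins against 12 (0.0093), 12 of 17 heat shock genes against 2 (0.0337) and 11 of 13 mitochondrially encoded genes against 1 (0.0496). With an estimated correlation none of these was called (adjusted p = 0.501 for respiratory chain, proteasome, replication and mitochondrially encoded genes, adjusted p = 0.713 with an estimated correlation for cytosolic ribosomal proteins and 0.321 for heat shock). The mitochondrial call was also lost with TMM factors (adjusted p = 0.0754). The other counts were the same adjusted over the list alone.

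Lists not called between the drugs were p53 targets (13 higher and 7 lower of 22, camera adjusted p = 0.24), ATF4 targets (15 and 6 of 29, 0.24), DNA repair (14 and 8 of 36, 0.599), mitosis (20 and 7 of 35, 0.245), histones (10 and 4 of 15, 0.32), pro-apoptotic (12 and 8 of 23, 0.649) and anti-apoptotic genes (6 and 2 of 9, 0.429), antioxidant enzymes (10 and 8 of 19, 0.948), endoplasmic reticulum stress (8 and 12 of 24, 0.363), interferon (8 and 8 of 21, 0.649), autophagy (8 and 14 of 26, 0.14), ferroptosis (9 and 8 of 18, 0.856), glycolysis (6 and 6 of 18, 0.454), supporting cell (6 and 5 of 14, 0.977) and drug handling genes (5 and 7 of 12, 0.32). The same counts were found adjusted over the list alone. With TMM factors the higher and lower counts became 13 and 13 for DNA repair, 5 and 9 for interferon, 7 and 9 for ferroptosis, 4 and 10 for glycolysis and 5 and 5 for supporting cell genes. For interferon and ferroptosis genes the camera direction was opposite in sign to the median and the mean. Among the genes fixed in advance, Ccnb1 (58.6 and 59.1 FPKM with cisplatin and neomycin, adjusted p = 0.793) and Ccnd1 (52.3 and 54.0 FPKM, adjusted p = 0.416) were not called, while quantile normalization called both (adjusted p = 5.4e-04 and 9.3e-04) and TMM factors called Ccnd1 (0.0462). Mki67 was lower with cisplatin than with neomycin by 0.76 ± 0.07 on the log2 scale.

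The drugs called many of the same genes, in like and in opposite directions about as often as independent lists would. Both raised 1872 genes (1877 for independent lists of these sizes) and both lowered 979 (922), while 2654 genes were called in opposite directions (2641), 1420 up with cisplatin and down with neomycin and 1234 the reverse. With TMM factors both raised 1319 and both lowered 1454, and 2693 were called in opposite directions, so the balance of shared rises and falls depended on the scaling. At 2-fold or more, 23 genes rose with both (6.8 for independent lists), 17 fell with both (2.3) and 11 moved oppositely (7.9). Across genes, which are not independent replicates, the fold changes correlated at 0.06. Unchanged groups simulated against the same PBS libraries gave 0.5, because shared controls alone create a correlation. The covariance was 0.0139 against 0.0024 simulated, a difference of 0.0116. The simulated groups shared on average 0.01 rises, 0.01 falls and 0 opposite calls, because unchanged groups call almost no genes. Those counts therefore cannot tell how much of the overlap the shared libraries give. Part of the overlap may come from the shared PBS libraries, since 3 of them cannot be split into parts of at least 2. Cdkn1a, Myc, Plk2 and Pmaip1 rose with cisplatin and fell with neomycin, and Hmgcs1, Clec3b, Col23a1 and Col6a1 did the reverse.

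Few hair cell genes passed the filter, which in view of the uncertain gene models does not show low expression. Of 36 listed hair cell markers 21 were matched and 4 passed the filter. Myo7a, a stereocilia myosin, was at 0.88 ± 0.04 FPKM in PBS, 1.33 ± 0.12 in cisplatin (log2 fold change 0.31 ± 0.07) and 2.54 ± 0.11 in neomycin (0.91 ± 0.07). Myo6 fell by 0.92 ± 0.07 with cisplatin on the log2 scale. Cib2 rose by 0.55 ± 0.09 with neomycin. With cisplatin Cib2 fell by 0.24 ± 0.09, a call lost with no filter (adjusted p = 0.0883), against a 1.5-fold change (1.00), without PBS replicate 1 (adjusted p = 0.0938), PBS replicate 2 (0.104) or cisplatin replicate 3 (0.14) and with voom (0.0812). Whrn fell by 0.31 ± 0.08 with cisplatin, and its rise of 0.19 ± 0.08 with neomycin (adjusted p = 0.0461) was lost under 13 of the alternatives, including TMM factors (adjusted p = 0.101). All 4 were lower with cisplatin than with neomycin. These counts were the same adjusted over the list alone, 1 higher and 3 lower with cisplatin and 3 higher and 0 lower with neomycin. Pou4f3 and Otof, chosen after their values were seen, averaged 0.00 FPKM in PBS.

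Few epithelial, glial, neuronal or immune markers passed the filter, and the same limit of the gene models holds for them. Of 13 epithelial and 11 glial markers 1 each passed the filter, Epcam and Pmp22, and of 14 neuronal and 13 immune markers none did. Epcam rose by 0.55 ± 0.14 with neomycin, was called lower with cisplatin when adjusted over the list alone or with TMM factors but not in the main test, and Pmp22 fell by 0.40 ± 0.07 with cisplatin on the log2 scale. Among immune genes, Cd68 averaged 0.20 ± 0.06 FPKM in PBS, 0.19 ± 0.04 in neomycin and 1.68 ± 0.20 in cisplatin, and Fcer1g 0.16 ± 0.06, 0.05 ± 0.05 and 1.31 ± 0.10 FPKM (SD, n = 3). Neither was tested, and both were chosen after their values were seen.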

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

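The tests of scaling and of cycling cells and the count of splits below were chosen only after the results were seen. Groups of 3 libraries were not tested for single outlying samples.

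Several lists and genes moved in opposite directions with the drugs. Those given here were kept only if the direct comparison of cisplatin with neomycin called them too, so that call is no further support. The fold changes of that comparison use no PBS library, although its spread does. For a gene, however, its fold change is just the difference between the changes against PBS. The median log2 fold change of the list members, cisplatin against neomycin, was 2.19 for immediate early genes, 1.16 for ribosome assembly, 0.58 for mitochondrial ribosomal proteins and 0.44 for proteasome subunits, and -0.91 for cholesterol synthesis. Among genes fixed in advance the log2 fold change was 1.91 for Cdkn1a, 1.51 for Ddit3 and 1.22 for Mdm2. No list difference was called with an estimated correlation.

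Of the 10 splits of the 6 libraries of each comparison, 1, the real one, called as many genes. In fits of only those 6 libraries the real counts were 8258 genes for cisplatin against PBS, 6648 for neomycin against PBS and 8661 for cisplatin against neomycin, and the highest of the other splits called 0 in each. These 10 splits are too few for a share under 0.05. Each of the other splits also mixes both treatments, so the difference between treatments enters the spread and few calls were likely in advance.

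Neomycin raised cholesterol synthesis genes such as Hmgcs1 and lowered ATF4 targets such as Trib3 and ribosome assembly genes such as Rrp12. ATF4 targets also fell with cisplatin, 21 lower and 4 higher of 29. Between the drugs that list was not called (camera adjusted p = 0.24). The shared PBS libraries may therefore contribute to its fall, which was not tested. TMM factors lowered the neomycin changes by a median of 0.05, and 23 cholesterol genes stayed higher. The median of the list was 0.79, and 0.75 with TMM factors. That these factors moved it so little argues against the authors' scaling as the source of the rise. A shift this small could hardly undo the rise, so the count that stayed higher adds little. A downward shift could not undo a fall. The 29 ATF4 targets and 25 ribosome assembly genes that stayed lower with TMM factors therefore do not test the scaling. The 29 higher mitosis genes, beside 2 lower, argue against a smaller share of cycling cells only if these mRNAs follow cycling. With cisplatin 30 of 35 rose and 3 fell although the cell cycle inhibitor Cdkn1a rose as well. Lower mTORC1 activity, which would lower fatty acid synthesis genes, was not borne out, since 13 of them had a median of 0.029 (percentile 61.2 of 10000 random lists matched on expression), which by the bound set before the value was seen counts against it. That bound was too loose to exclude it, because members went both ways, 5 higher, such as Fasn (0.45 ± 0.05), and 4 lower, such as Srebf1 (-0.47 ± 0.06). Both genes and this reading were chosen after the values were seen. Of the 15 listed 1, Me1, was also in the NRF2 list and its value had been seen.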

How the results depend on the processing

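The voom test was chosen only after the data were seen, and the other alternatives were planned. A count test planned for deposited counts was not run because the values are FPKM.

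Calls of named genes depended little on most settings. Most of these genes were taken because they were called with large changes, which made this stability likely in advance. Of 416 named results 104 lost the call against a 1.5-fold change, as that test asks for more, and for 312 direction and side of the threshold were the same, some of which were not called in either test. That test called 1892 genes for cisplatin against PBS, 426 for neomycin against PBS and 2637 for cisplatin against neomycin. The 2-fold count of neomycin against PBS, 182, became 380 with a pseudocount of 0.1, which shrinks low genes less, and 114 with a minimum of 5 FPKM, which tests fewer genes. It became 418 with voom, which changes several steps together, and the cause was not tested. Quantile normalization ended 10 named calls, added 2 and turned Slc31a1 between the drugs to -0.031 (adjusted p = 0.466), and the cause was not tested. TMM factors ended 3 named calls and added 1. Over all tested genes they shared 7283, 6451 and 8161 calls with the main test, which called 8216, 6973 and 8598. These counts are for cisplatin against PBS, neomycin against PBS and cisplatin against neomycin.

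List calls depended on how correlation between genes was treated. With an estimated correlation 0 lists were called in each comparison, against 15 for cisplatin, 14 for neomycin and 14 between the drugs. Fry, which does not compare a list with other genes, called 24, 27 and 28. The call of mitochondrially encoded genes between the drugs (adjusted p = 0.0496) was lost without PBS replicate 1 (0.0504), PBS replicate 2 (0.0602), PBS replicate 3 (0.0534), neomycin replicate 2 (0.0518), cisplatin replicate 2 (0.0658) or cisplatin replicate 3 (0.0650).

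Whether the replicate numbers pair the samples is unclear. Deviations of same-numbered samples correlated at -0.05 to 0.30. Replicate 1 of each group correlated best with replicate 1 of the other groups (0.13 to 0.30). PBS replicate 3 correlated best with replicate 3 of neomycin (0.19) and of cisplatin (0.17). PBS replicate 2, however, also correlated best with replicate 3 of neomycin (0.19) and of cisplatin (0.16). With the number as a block 8424, 7261 and 8746 genes were called in the 3 comparisons, against 8216, 6973 and 8598 without it. The lists called with the block numbered 15, 14 and 14. The block added the call of Atf3 for cisplatin against PBS (adjusted p = 0.0406) and ended that of Whrn for neomycin against PBS (0.0552), and it changed no other call of a named gene or list.

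Depth limited little, since every tested gene had at least 99 reads summed over the libraries, but genes under 1 FPKM, including most of the matched hair cell markers, were not tested.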

Other observations

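The tests of scaling, of ATF4 targets and of cisplatin against neomycin below were chosen only after the results were seen, and the lists used here were written after the main results had been seen but before their own values were.

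KEGG terms of the deposited table were tested after the data were examined, and some share members with the lists, such as aminoacyl-tRNA synthesis with ATF4 targets. With cisplatin 102 of 125 spliceosome genes rose and 12 fell (camera adjusted p = 4.2e-06; adjusted p = 0.409 with an estimated correlation), and 37 of 47 cytosolic DNA-sensing genes rose and 2 fell (camera adjusted p = 0.0019; adjusted p = 0.409 with an estimated correlation). Of 115 axon guidance genes 68 fell and 25 rose (camera adjusted p = 3.6e-04; adjusted p = 0.468 with an estimated correlation). With neomycin 30 of 44 aminoacyl-tRNA synthesis genes fell and 5 rose (camera adjusted p = 5.9e-05; adjusted p = 0.709 with an estimated correlation), and 62 of 98 phagosome genes rose and 9 fell (camera adjusted p = 4.1e-04; adjusted p = 0.694 with an estimated correlation).

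Genes that span long stretches of the genome were lower with cisplatin. The idea came from Gpc6, Cdh13, Ptprg, Ptprk and Dock1 and from the axon guidance term, so a list of 72 other long genes was written from general knowledge, without measured spans, and shared no member with the other lists. Of 51 tested 49 fell and 1 rose, including Tenm4 (-2.42 ± 0.06), Exoc6b (-2.36 ± 0.08) and Lpp (-2.01 ± 0.09), which were chosen after their values were seen, with a median of -1.26 (random lists matched on expression, -0.11 to 0.25). Exonic length is argued against, since lists matched on it too reached only -0.24 at their 2.5% point. The PBS libraries may contribute, since the median with neomycin was -0.056 (percentile 0.64), but not as the whole source, since cisplatin against neomycin gave -1.12 with 48 lower and 2 higher. Blocked elongation at platinum crosslinks, which long genes would meet more often, is a candidate explanation that these tests did not separate from a regulated change.

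Transcripts of mitochondrial DNA were lower with neomycin. With TMM factors 12 of 13 stayed lower. This does not test the authors' scaling, because these factors lowered the neomycin changes (median 0.05) and could not undo a fall. A mitochondrial stress response through ATF4 is argued against by the 29 ATF4 targets that were lower. That reading assumes that the shared PBS libraries were not high in ATF4 targets, most of which fell with cisplatin too. Lower expression of nuclear genes of mitochondrial transcription and RNA handling may contribute. A list of them, which also held mitochondrial DNA replication genes such as Polg and Twnk, had 16 of 24 tested lower and 1, Polg, higher. Its median was -0.24 (percentile 0.04). The largest fall was that of Tfb2m (-0.77 ± 0.06), also chosen after its value was seen. With cisplatin 19 of the listed genes rose and 2 fell (median 0.44), while 3 mitochondrial mRNAs rose and 5 fell (1 and 7 with TMM factors). Most mitochondrial mRNAs thus did not rise along with the listed genes there, and a link between them was not tested. Direct action of an aminoglycoside on mitochondria was not tested.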
